A study of Homo sapiens with 4 samples.

How the data were processed

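The labels give total RNA, extracted with Trizol and sequenced on Illumina instruments, from U2OS and 143B cells infected with lentiviral hairpins. The labels place 1 library in each of 4 groups: NC and shMETTL14 of each line. The column headers give the same hairpin number to the shMETTL14 libraries of both lines, and the hairpin's sequence is not given in the sources used here.

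The deposited values are FPKM, fragments per kilobase of transcript, scaled to the mapped fragments of the library, computed by the authors with 1 value per transcript, per the file headers. The submitters' processing notes name Bowtie 0.12.2 and the builds hg19 and GRCh37, and also the mouse build mm8 with no role given. The program that estimated transcript levels is not given in the sources used here. Transcript identifiers carry the suffixes of GENCODE annotation lifted to another build. For every listed transcript at least 1 of the 4 libraries reached 0.5 FPKM, so weaker transcripts are not in the tables. Of 13610 genes found in GENCODE release 29, 13593 are protein coding. No scaling between libraries beyond the authors' own was applied in the main analysis.

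FPKM values are not counts, so no count model was used. The low values of genes with 1 listed transcript were searched for steps of whole fragments. Between 28.3% and 31.4% of them lay within 2% of a whole multiple of the commonest step, against 19.0% to 22.7% after a random shift, so fragments were not recovered and the depth of the libraries is unknown. Between 469 and 833 genes were listed at 0 per library, and no ratio of FPKM values is given against a value of 0. On the log2(FPKM + 1) scale such genes keep a value, whose size depends on the pseudocount.

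Gene values were the sum of a gene's transcript FPKM. Symbols came from a table of Ensembl identifiers and matched 13588 of 13716 genes. The annotation at hand, GENCODE release 29, is on another build than the files, so it was used only for transcript lengths, sequences, exon sharing between genes and readthrough flags, and no coordinates are given. Lengths were found for 99.5% of 42562 transcripts, and 582 genes share exons with another listed gene or hold readthrough transcripts.

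Within a line, log2(FPKM + 1) of the 2 libraries was compared by a size rule of 2-fold among genes with a mean of at least 1 FPKM, with no test. Over both lines, limma 3.58.1 in R 4.3.3 was fitted with a trend to log2(FPKM + 1), with cell line as a block, to 12036 genes with a mean of at least 1 FPKM over the 4 libraries. Its tests were two-sided with Benjamini-Hochberg adjustment. Its residual is the difference between the lines' responses, with 1 degree of freedom per gene. The labels do not say whether the libraries of a line came from separate cultures beyond the infection. For each of 33 gene lists fixed before the data were examined, the median log2 fold change was placed among 10000 random lists of the same size matched on expression in 20 bins, for lists with at least 5 measured genes, as a description of these libraries. The haematopoietic and endothelial marker lists had too few measured genes in both lines, and the chondrocyte and epithelial lists in 143B. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

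Genes were named by a rule fixed before the data were examined. It takes METTL14, the m6A lists and MN1, which was recalled from published work as a METTL14 target in osteosarcoma and not taken from the labels. Per line it takes the 8 genes with the largest increase and the 8 with the largest decrease among genes with a mean of at least 5 FPKM. It takes the 10 genes higher and the 10 lower in both lines by the smaller absolute log2 fold change, and the 3 per pattern that moved at least 2-fold in opposite directions. From each list it takes up to 3 members highest and 3 lowest per line among those at least 2-fold different. Its part on genes past the joint fit's threshold named none.

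The procedures were tested on simulated data. The size rule recovered 200 of 200 genes planted at 3-fold in copies of the NC libraries without added noise, which checks the code and not its power. In the joint fit of 12036 genes with simulated normal noise, limma recovered 62.7% of genes planted at 2-fold and 100% of those at 4-fold and 16-fold. It made 11 false calls there, and 0 calls without planted genes. Genes of similar expression were given the same noise, unlike real genes, so these shares do not measure the power of the real fit. A list of 20 genes shifted by 0.5 in U2OS was at percentile 100, and 3.5% of random lists lay outside the central 95%.

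Sequence heptamers were scored against the log2 fold changes of 6772 genes with a mean of at least 5 FPKM in both lines and a 3' UTR of at least 20 bases in the transcript with the highest mean. The fold changes were length-weighted, converted to normal ranks and corrected for the length and GC content of the 3' UTR. A heptamer's score is the mean of its genes' values times the root of their number, for 16098 heptamers held by at least 30 genes. In 20 runs with shuffled fold changes the largest absolute score was 4.64. A shift of -0.15 planted on 505 genes with 1 heptamer gave that heptamer the lowest score in 20 of 20 runs.

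Alternatives fixed before the data were examined were median-of-ratios and upper-quartile scaling, no filter or a mean of at least 5 FPKM, pseudocounts of 0.1 and 5, thresholds of 1.5-fold and 4-fold, and for the joint fit no block or no trend. Alternatives chosen after seeing the data were the largest transcript alone, length-weighted gene values, a mean of at least 20 FPKM, leaving out genes that share exons or hold readthrough transcripts, leaving out genes with either of 2 heptamers, a correction of fold changes for GC content, and the difference between the lines in the joint fit. Length-weighted values are sums of FPKM times transcript length over the gene's mean length, which follow the fragments assigned to a gene.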

Results

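RNA was sequenced from U2OS and 143B, 2 established human osteosarcoma cell lines, each infected with a lentivirus carrying a control hairpin (NC) or a short hairpin RNA against METTL14 (shMETTL14). METTL14 is the partner of METTL3 in the nuclear complex that writes N6-methyladenosine (m6A) on mRNA. The study asked which genes differ between NC and shMETTL14 cells. Each of the 4 groups held 1 library, so no difference within a line has a replicate check, and each fold change below compares 2 libraries, not 2 conditions. The tables list 42562 transcripts of 13716 genes in FPKM, and gene values are sums over transcripts. Summed values came to 292879 and 286202 FPKM in the U2OS NC and shMETTL14 libraries and to 315583 and 310014 FPKM in those of 143B. Sequencing depth is unknown, so a value's counting error is unknown too. Log2 fold changes are on the log2(FPKM + 1) scale, which understates differences of weakly expressed genes.

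METTL14 itself was lower in the shMETTL14 library of both lines. Its level was 4.36 FPKM in U2OS NC and 1.90 FPKM in U2OS shMETTL14, a log2 fold change of -0.89. In 143B it was 5.05 FPKM in NC and 1.65 FPKM in shMETTL14, a log2 fold change of -1.19. Both listed METTL14 transcripts were lower in both lines. METTL3, the catalytic subunit, stood at 4.67 and 1.63 FPKM in U2OS (log2 fold change -1.11) and at 8.99 and 6.57 FPKM in 143B (-0.40). WTAP, which holds the writer complex in nuclear speckles, had log2 fold changes of -0.07 in U2OS and 0.47 in 143B. Among erasers and readers of m6A, the reader YTHDF2 was at 5.96 FPKM in U2OS NC and 14.15 in U2OS shMETTL14. The demethylase FTO was at 12.88 and 4.85 FPKM in the same libraries, but its log2 fold change was -0.08 in place of -1.25 when transcripts were weighted by length. ALKBH5, the other demethylase, had log2 fold changes of 0.01 and 0.42 in U2OS and 143B.

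MN1, a transcriptional coregulator, was named before the data were examined because it was recalled from published work as a METTL14 target in osteosarcoma. Whether that work used these libraries was not checked, so MN1 is no independent check of it. MN1 was lower in both shMETTL14 libraries, by under 2-fold in 143B, and its adjusted p in the limma joint fit was 0.629. It went from 25.31 to 4.64 FPKM in U2OS, a log2 fold change of -2.22, and from 2.36 to 1.11 FPKM in 143B, a log2 fold change of -0.67.

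**Figure D1:**
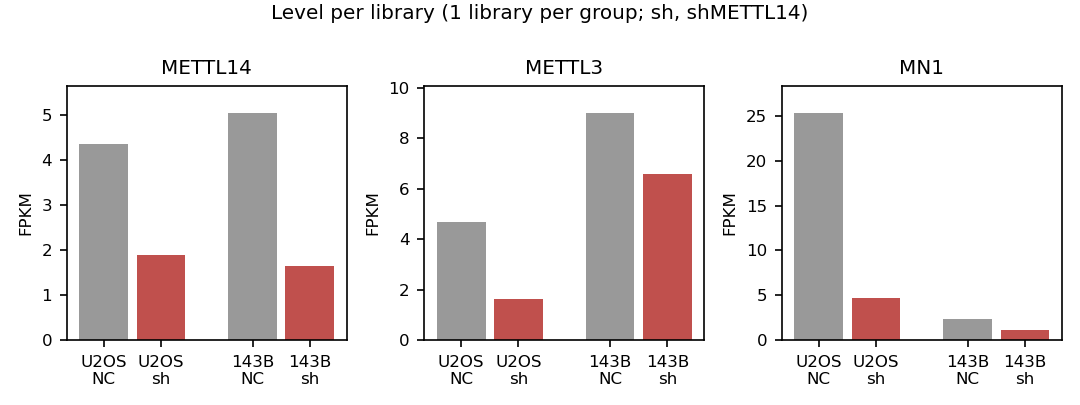
Levels of METTL14, METTL3 and MN1 in FPKM, 1 bar per library, with the NC libraries in grey and the shMETTL14 libraries in red; there are no replicates and so no error bars. METTL14 was at 4.36 and 1.90 FPKM in U2OS and at 5.05 and 1.65 FPKM in 143B, and all 3 genes had a lower bar in shMETTL14 than in NC of the same line.

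In U2OS, MYC, MMP3 and CCL20 were among the genes with the largest increases, and LMCD1, IQGAP1 and AUP1 had the largest decreases, among genes with a mean of at least 5 FPKM. MYC, the growth-promoting transcription factor, was at 15.76 FPKM in NC and 82.69 in shMETTL14 (log2 fold change 2.32). The stromelysin MMP3 was at 4.89 and 27.99 FPKM, and the chemokine CCL20 at 2.88 and 17.61 FPKM. VPS35, a subunit of the retromer sorting complex, was at 1.00 and 21.11 FPKM, EIF2B5 of the translation factor eIF2B at 1.31 and 11.24, and CYBC1, a chaperone of the phagocyte oxidase, at 3.46 and 23.16. H4C15 went from 0.02 to 16.95 FPKM and PSG4 from 1.22 to 9.20, but both belong to families of near-identical genes between which reads can be split, so their values are uncertain. On the lower side, the LIM protein LMCD1 went from 35.87 to 2.74 FPKM, the scaffold protein IQGAP1 from 32.09 to 2.51 and the lipid droplet protein AUP1 from 19.06 to 1.14. The collagenase MMP13 went from 13.10 to 0.86 FPKM and the chemokine CXCL14 from 30.53 to 4.51. SH3GLB2, LDLRAD4 and MRFAP1 completed the 8 largest decreases, with log2 fold changes of -2.80, -2.50 and -2.46.

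By the size rule of 2-fold, 335 genes were higher and 376 lower in the U2OS shMETTL14 library, of 11890 with a mean of at least 1 FPKM. With a mean of at least 5 FPKM required, the total was 408 in place of 711, and with a pseudocount of 0.1 it was 1098. Using each gene's largest transcript alone it was 1645.

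Genes of bone and connective tissue matrix stood lower as a group in U2OS shMETTL14. Of 22 measured collagen and matrix protein genes, 19 were lower, 5 of them at least 2-fold, and the list's median log2 fold change of -0.44 was at percentile 0.00 of 10000 random lists matched on expression. COL1A1, the main collagen of bone, was at 309.5 FPKM in NC and 116.8 in shMETTL14. SPARC, the bone matrix glycoprotein osteonectin, was at 361.0 and 147.1 FPKM and COL3A1 at 56.84 and 22.90. In 143B the list's median was -0.17 at percentile 3.03, inside the central 95%, with 13 of 20 members lower, 2 at least 2-fold higher and 1 at least 2-fold lower. It lay outside with a pseudocount of 5, with a mean of at least 5 FPKM required and with length-weighted values. Chondrocyte genes had a median of -0.63 over 6 measured members (percentile 0.29), and retinoic acid pathway genes a median of -0.27 over 13 (percentile 1.29), each with no member at least 2-fold different.

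Inflammatory genes were higher in the same library. All 11 measured NF-kB targets and inflammatory mediators were above 0, with a median log2 fold change of 0.79 at percentile 100, and 4 were at least 2-fold higher, among them IL1A at 0 and 2.21 FPKM, whose size depends on the pseudocount. CCL2, which recruits monocytes, was at 7.57 FPKM in U2OS NC and 28.65 in shMETTL14, and the neutrophil chemokine CXCL8 at 7.75 and 28.64. In 143B the inflammatory list had a median of -0.12 at percentile 15.1, with 8 of 15 members below 0, 5 of them at least 2-fold, and none at least 2-fold higher. Targets of p53 in U2OS had a median of 0.30 at percentile 99.84, with 18 of 21 above 0. In 143B their median was -0.07 at percentile 31.2, with 12 of 20 below 0. Among these targets in U2OS, the stress cytokine GDF15 was at 20.10 and 86.43 FPKM. The death receptor gene TNFRSF10B was at 8.77 and 30.74 FPKM, and PLK3 at 1.75 and 5.87 FPKM. Genes of the unfolded protein and amino acid stress response in U2OS had a median of 0.30 at percentile 100, with 18 of 21 above 0 and none at least 2-fold. For MYC and ribosome biogenesis genes the median was 0.43 at percentile 100, with 17 of 19 above 0. MYC and the ribosome assembly factor RRP12 were at least 2-fold higher, but RRP12 had a log2 fold change of 0.85 in place of 1.02 with length-weighted values.

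Replication genes had a median of 0.18 (percentile 98.48, 19 of 26 above 0) and interferon-stimulated genes one of 0.37 (percentile 99.25, 8 of 13 above 0). Epithelial markers had a median of 0.67 (percentile 99.82), but rested on 5 measured genes of which 3 were above 0, and KRT14 was at least 2-fold lower. Interferon-stimulated genes fell inside the central 95% with median-of-ratios scaling, with a pseudocount of 5 and with a mean of at least 5 FPKM required. Replication, chondrocyte and epithelial genes did so, or had too few genes left, with the stricter filter. In all, 10 of 31 lists with at least 5 measured genes lay outside the central 95% in U2OS, where 1.55 would by chance if lists held unrelated genes and shared none. Members of a list are often regulated together and some lists share genes, so this is not the number to be found with no effect.

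In 143B, the genes with the largest differences were other ones. LPCAT1, an acyltransferase of lung surfactant synthesis, was at 43.02 FPKM in NC and 0.44 in shMETTL14, the largest decrease (log2 fold change -4.94). The interleukin-10 receptor gene IL10RA went from 22.19 to 0.10 FPKM, the cytokine IL1B from 26.15 to 1.97, and the tissue plasminogen activator PLAT from 62.97 to 7.73. LMNB1, the nuclear lamin, was at 38.69 and 3.71 FPKM. The actin regulators TWF1 and ARPC2 went from 33.84 to 4.92 and from 112.48 to 21.99 FPKM. RPL36A-HNRNPH2 went from 102.16 to 16.31 FPKM, but it is a readthrough gene that shares exons with its neighbours, so its value is uncertain. On the higher side, the splicing kinase PRPF4B went from 2.07 to 26.81 FPKM, the forkhead factor FOXD1 from 1.37 to 15.37 and the zinc finger protein ZFAND5 from 6.97 to 48.28. The ceramide synthase CERS5 was at 1.11 and 14.37 FPKM, TLCD3A at 1.16 and 15.83, NOL12 at 4.05 and 29.46, SHQ1 at 1.23 and 10.82, and FAM136A at 5.09 and 31.26. With length-weighted values the log2 fold change of CERS5 was 1.74 in place of 2.86, and that of NOL12 1.61 in place of 2.59.

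The size rule gave 311 higher and 378 lower genes of 11308 in 143B. The total of 689 was 416 with a mean of at least 5 FPKM required, 1124 with a pseudocount of 0.1 and 1569 with each gene's largest transcript alone.

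Matrix remodelling genes were lower as a group in 143B shMETTL14, with 14 of 20 measured members below 0 and a median of -0.38 at percentile 0.06. The urokinase PLAU was at 312.0 FPKM in NC and 106.7 in shMETTL14, and the metalloprotease ADAM19 at 32.58 and 12.86. MMP3 of the same list was higher, at 4.56 and 18.53 FPKM. YAP-TEAD targets had a median of -0.31 at percentile 0.91, with 11 of 14 below 0. The matricellular genes CCN1, at 291.2 and 107.5 FPKM, and CCN2, at 253.8 and 97.24 FPKM, were among the 3 at least 2-fold lower. With length-weighted values the YAP-TEAD list lay inside the central 95%.

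Amino acid and protein folding stress genes were lower in 143B shMETTL14, with 16 of 21 below 0 and a median of -0.34 at percentile 0.14. CTH, the enzyme that makes cysteine from cystathionine, was at 10.86 FPKM in NC and 1.41 in shMETTL14. Asparagine synthetase ASNS was at 92.17 and 26.78 FPKM and the cystine transporter SLC7A11 at 8.25 and 2.22. SLC7A11 was also the one NRF2 target at least 2-fold lower, in a list with a median of -0.26 (percentile 1.75, 12 of 17 below 0). That list lay inside the central 95% with a pseudocount of 5, with a mean of at least 5 FPKM required and after correction for GC content. The epithelial-mesenchymal list had a median of -0.22 (percentile 1.90, 11 of 18 below 0) and lay inside the central 95% with median-of-ratios scaling and with length-weighted values.

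Cytosolic ribosomal protein genes were slightly lower in 143B shMETTL14, 23 of 24 below 0, with a median of -0.23 at percentile 1.27. RPLP0 was at 995.4 FPKM in NC and 310.0 in shMETTL14, a difference that lay mostly in 1 of its 11 listed transcripts, at 815.4 and 199.7 FPKM. Mitochondrially encoded genes had a median of 0.32 at percentile 99.94, with 10 of 13 above 0. MT-ND6, the one listed gene at least 2-fold higher, was at 138.6 and 546.7 FPKM in 143B and at 610.8 and 586.8 FPKM in U2OS. Their share of all FPKM was 9.30% in 143B NC and 10.97% in 143B shMETTL14.

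MYC and ribosome biogenesis genes were also higher in 143B, with 14 of 19 above 0 and a median of 0.44 at percentile 99.98, while MYC itself went from 21.94 to 5.34 FPKM. POLR1B, a subunit of RNA polymerase I, went from 18.81 to 4.10 FPKM. Mitosis genes had a median of 0.27 (percentile 99.65, 20 of 25 above 0) with none at least 2-fold different. Glycolysis and hypoxia genes had a median of 0.21 (percentile 99.30, 17 of 27 above 0), with NDRG1 at least 2-fold lower, and lay inside the central 95% with a mean of at least 5 FPKM required. In 143B, 10 of 29 lists lay outside the central 95%, where 1.45 would by chance under the same assumption.

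**Figure D2:**
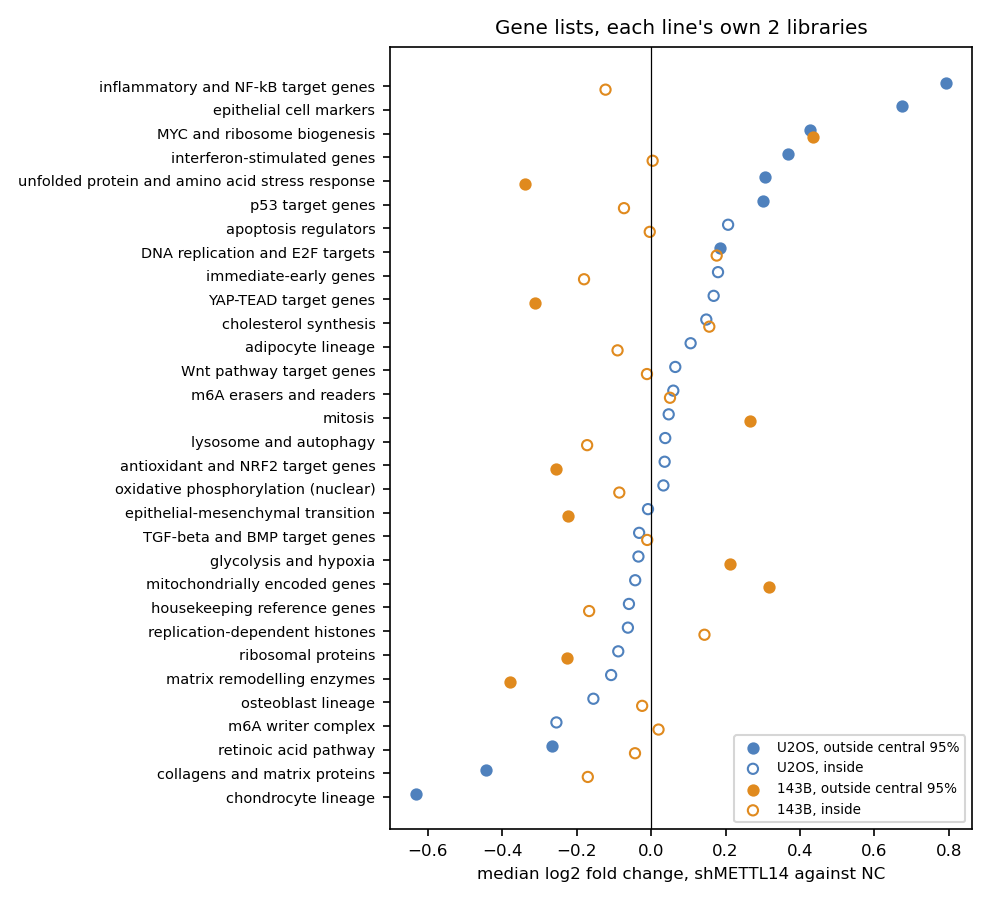
Median log2 fold change of shMETTL14 against NC for each gene list with at least 5 measured genes in U2OS, as blue points for U2OS and orange points for 143B; filled points lie outside the central 95% of 10000 random lists matched on expression. MYC and ribosome biogenesis genes had medians of 0.43 and 0.44 in the 2 lines, and the stress response list medians of 0.30 and -0.34.

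Across both lines, 40 genes were at least 2-fold higher and 34 at least 2-fold lower in both shMETTL14 libraries, of 10590 genes measured in both. Independent lists of the same sizes would share 7.08 and 9.08 genes. The higher genes included FOXD1, from 3.58 to 16.37 FPKM in U2OS and from 1.37 to 15.37 in 143B, and MMP3, at log2 fold changes of 2.30 and 1.81. SMG8, of the nonsense-mediated decay machinery, had log2 fold changes of 1.62 and 2.18. The chromatin reader SPIN1 had 2.02 and 1.52, the ubiquitin ligase SMURF2 2.07 and 1.42, and the stress-responsive factor ATF5 1.32 and 1.63. STEAP1, TSSC4, CWF19L1 and ATP6V0D1 followed, all at 1.21 or more in both lines. With length-weighted values ATP6V0D1 had log2 fold changes of 0.71 and 1.14, and ATF5 had 2.23 and 1.68.

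Genes lower in both lines were led by MRFAP1 and IQGAP1, ranked by the smaller of the 2 differences. MRFAP1 went from 62.50 to 10.54 FPKM in U2OS and from 130.56 to 28.33 in 143B. IQGAP1, which links signalling to the cytoskeleton, had log2 fold changes of -3.24 and -2.15, ARPC2 of the Arp2/3 complex -1.50 and -2.30, and the actin-binding protein TWF1 -1.46 and -2.56. The deubiquitinases USP11 and USP7 had log2 fold changes of -1.52 and -1.50, and of -1.45 and -1.47. RNASEH2A, the catalytic subunit of RNase H2, had -1.42 and -2.24, the sphingolipid regulator ORMDL3 -2.13 and -1.20, and UPF3A -1.20 and -1.37. The palmitoyltransferase ZDHHC20 had -1.27 and -1.41.

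Another 39 genes were at least 2-fold different in opposite directions, 20 of them higher in U2OS and 19 higher in 143B, where independent lists would share 8.60 and 7.48. MYC, the guanine nucleotide exchange factor TRIO and the dynactin subunit ACTR10 were higher in U2OS and lower in 143B. The mitochondrial ribosomal protein genes MRPL34 and MRPL10, with EPDR1, were lower in U2OS and higher in 143B. Over the 10590 genes, the log2 fold changes of the lines had a Pearson correlation of 0.12 and a Spearman correlation of 0.14, and 56.1% of genes with nonzero values had the same sign. These correlations are across genes, which are not independent replicates. With each gene's largest transcript alone, 217 genes went the same way and 205 opposite ways.

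**Figure D3:**
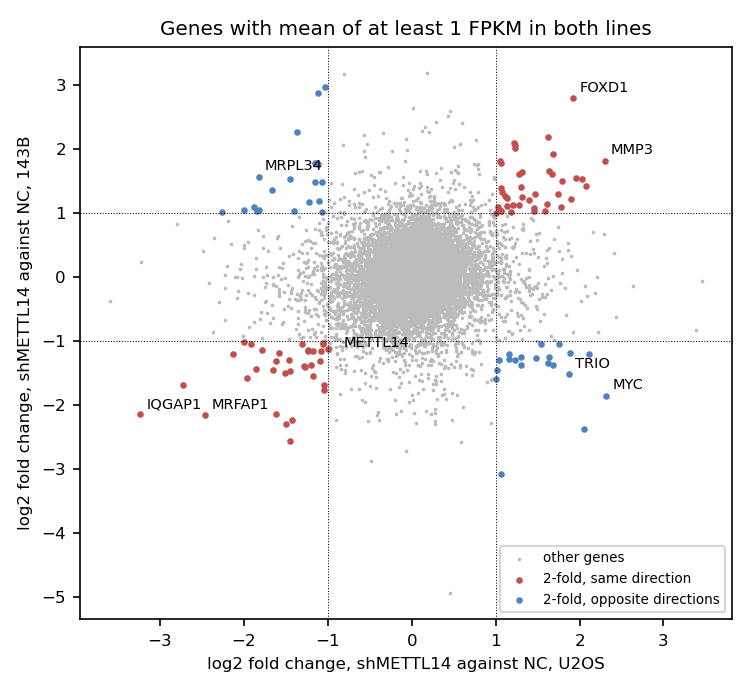
Log2 fold change of shMETTL14 against NC in U2OS (horizontal) and 143B (vertical) for 10590 genes with a mean of at least 1 FPKM in both lines; dotted lines mark 2-fold. The 74 genes in red went at least 2-fold the same way in both lines and the 39 in blue opposite ways.

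Taking the lines as replicates, with cell line as a block and 1 residual degree of freedom, limma called 0 of 12036 genes at an adjusted p of 0.05. The smallest adjusted p was 0.387, that of MRFAP1, whose fitted log2 fold change was -2.31. The 0 calls therefore do not exclude large changes shared by the lines. At an unadjusted p under 0.05 there were 888 genes, 7.38% of those tested. Fitted to the difference between the lines instead, limma also called 0 genes and gave 459 at an unadjusted p under 0.05. Without the block it called 0 genes, with 75 at an unadjusted p under 0.05, and limma without a trend called 0 with 812.

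Adjusted over the list alone, 9 genes of 6 lists passed the same limma test, all with an adjusted p of at least 0.489 over all genes. The plan adjusted over all genes tested only, and no correction was made across the 33 lists. The rises and falls below therefore describe fitted values and are not calls. MMP3 rose, with a fitted log2 fold change of 2.06 ± 0.24 (SE) and an adjusted p of 0.00471 over its list. In the epithelial-mesenchymal list, the integrin ITGB3 fell (-1.46 ± 0.26, adjusted p = 0.0281), the transcription factor ZEB1 fell (-1.01 ± 0.24, adjusted p = 0.0359) and the hyaluronan receptor CD44 rose (0.89 ± 0.19, adjusted p = 0.0359). The lipid droplet protein PLIN2 (0.99 ± 0.22, adjusted p = 0.0267) and ATP6V0D1, a subunit of the lysosomal proton pump (1.28 ± 0.21, adjusted p = 0.0225), rose within their lists. The peroxidase PRDX1 fell within the NRF2 list, from 373.8 to 229.1 FPKM in U2OS and from 402.6 to 226.3 in 143B (adjusted p = 0.0314). Among reference genes often taken as stable, EEF1A1 (-0.97 ± 0.12, adjusted p = 0.0043) and B2M (-1.13 ± 0.25, adjusted p = 0.0393) fell. The other 27 lists had no gene past this threshold, and PRDX1 was chosen for naming after its values were seen. With length-weighted values EEF1A1 had log2 fold changes of -0.48 and -0.60, in place of -0.84 and -1.10.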

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

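The difference between the lines was not tested against replicates for any result here. A limma fit to that difference, with the shared change as its residual on 1 degree of freedom, called 0 of 12036 genes (smallest adjusted p 0.175), with 459 at an unadjusted p under 0.05. All tests of explanations in this part, and the bounds that decided them, were chosen after the result was seen. Every gene below was at least 2-fold higher in the shMETTL14 library of one line and at least 2-fold lower in that of the other; the value given is the log2 fold change in U2OS minus that in 143B.

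Among transcription and growth regulators, MYC had a difference of 4.18 and DUSP1, a phosphatase of MAP kinases, 2.596. The stress cytokine GDF15 had a difference of 4.42, the nuclear lamin LMNB1 4.14, TRIO 3.39 and ACTR10 2.89. For the apoptosis inhibitor XIAP it was 2.97 and for the chemokine CXCL8 2.82. The cytokine IL1A is listed at 0 in U2OS NC and 2.21 FPKM in U2OS shMETTL14, so its difference of 3.07 depends on the pseudocount. In the other direction, TLCD3A had a difference of -4.00, CERS5 -3.98, MRPL34 -3.39, EPDR1 -2.92, COL1A1 -2.42, MRPL10 -2.39 and the activin antagonist FST -2.30. COL1A1 was at 1.41 and 3.89 FPKM in 143B, against 309.5 and 116.8 in U2OS. With length-weighted values 5 of these genes were under 2-fold in one line: TLCD3A (-0.66) and FST (-0.69) and CERS5 (-0.98) in U2OS, and COL1A1 (0.65) and TRIO (-0.99) in 143B.

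The unfolded protein and amino acid stress list lay outside the central 95% of random lists in opposite directions, with medians of 0.30 in U2OS and -0.34 in 143B, a difference of 0.64. Scaling between the libraries as the source is argued against by the list's percentiles of 100 and 0.14, since a shift common to all genes moves the random lists alike. The smaller difference over median-of-ratios and upper-quartile scaling was 0.64. Those factors lay between 0.96 and 1.04, so they could move it only a little. A trend with GC content would have to shrink the difference on correction, and the corrected difference was 0.63. Assignment of fragments between transcripts is argued against in the same way, with a length-weighted difference of 0.66 over the 17 members with more than 1 listed transcript, against 0.59. What stays open is a response that differs between the lines, a difference in culture state between single libraries, and chance between them, none of which 1 library per group can test.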

How the results depend on the processing

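The scaling between libraries, the omission of a filter, length-weighted values, leaving out genes that share exons or hold readthrough transcripts, and leaving out genes with either heptamer kept each count of 2-fold genes within 1.5 times. Of these, the last 3 were chosen after seeing the data, as were the largest transcript alone, the mean of at least 20 FPKM, the GC correction and the line difference. Counts for U2OS, 143B and the same direction in both, 711, 689 and 74 in the main setting, moved further elsewhere. They were 408, 416 and 36 with a mean of at least 5 FPKM and 121, 113 and 5 with a mean of at least 20 FPKM, where fewer genes are compared. A pseudocount of 0.1 gave 1098, 1124 and 130, and one of 5 gave 197, 200 and 14. Thresholds of 1.5-fold gave 2128, 2363 and 360, and of 4-fold 69, 68 and 2. With the largest transcript alone they were 1645, 1569 and 217, and the correlation between the lines fell to 0.0450 from 0.12; the cause was not tested. Of the main calls, 81.3% in U2OS and 82.9% in 143B stayed at least 2-fold in the same direction with length-weighted values. These shares include genes with 1 listed transcript, which length weighting cannot change, so they overstate how well calls hold for the other genes.

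METTL14 was lower in both lines under each of the 5 alternatives run, and its log2 fold change in 143B was -0.60 with a pseudocount of 5, which shrinks weak genes by construction. No list that lay outside the central 95% changed sign under the 6 alternatives run. In U2OS the number of lists outside was 6 with a mean of at least 5 FPKM, against 10, all 6 among the 10. Lists gained in 143B were collagens and immediate-early genes, under 3 alternatives each, and lysosome and autophagy genes with length-weighted values, which in U2OS added matrix remodelling genes. The joint fit called 0 genes under each of 10 alternatives. Leaving out a line left 1 pair and no residual degrees of freedom, so no test was made. No named gene at least 2-fold different turned its direction in the alternatives run for it. The joint fit, with cell line as its block, is the paired analysis of 2 NC and shMETTL14 pairs; no pairing is possible within a line. With no counts, depth limits cannot be given.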

Other observations

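The percentiles of gene lists were planned before the data were examined. All other tests in this part, and the bounds that decided them, were chosen after the fold changes were seen. Survival genes differed between libraries in a mixed way. In U2OS shMETTL14 the inhibitors of apoptosis BIRC3 and BCL2 were higher, from 2.57 to 11.31 and from 1.15 to 4.41 FPKM, and the pro-apoptotic BMF went from 15.27 to 5.92. In 143B shMETTL14 the survival gene BCL2A1 went from 15.18 to 2.601 FPKM and the pro-apoptotic PMAIP1 from 18.98 to 7.68. The list's median log2 fold change was 0.21 in U2OS (percentile 97.14) and -0.00 in 143B (percentile 43.17).

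Single genes differed at least 2-fold in lists whose medians lay inside the central 95% of random lists, such as osteoblast lineage genes in 143B (median -0.02, percentile 49.52). DKK1, a Wnt antagonist, was at 21.64 FPKM in 143B NC and 90.91 in shMETTL14. SPP1, the bone matrix protein osteopontin, was at 15.52 and 4.40 FPKM, and TNFRSF11B, the decoy receptor osteoprotegerin, at 0.61 and 2.38. The immediate-early gene FOSL1 in U2OS was at 12.17 and 33.86 FPKM, and FOS of the same list at 10.41 and 2.30. In that list 3 genes were at least 2-fold higher and 2 at least 2-fold lower in U2OS. In U2OS, TXNRD1, which reduces thioredoxin, was at 85.88 and 240.8 FPKM, and the autophagy gene MAP1LC3B at 28.93 and 65.95.

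A sequence pattern joined the shMETTL14 libraries of the 2 lines. Of 16098 heptamers in 3' UTRs, CATTGAC and ATTGACA had the 2 lowest scores in each line taken alone, at -5.71 and -5.54 in U2OS and -5.74 and -6.43 in 143B. The next lowest score was -3.79 in U2OS and -4.50 in 143B, and the largest absolute score in shuffled data was 4.64. The -4.50 was that of TATTGAC, which holds ATTGAC as the first 2 do, so it is not a separate background. TATTGAC scored -2.57 in U2OS, and the next score in 143B was -4.095, of GATAAAC. In the difference between the lines CATTGAC and ATTGACA scored 0.74 and 1.66. The heptamers overlap as CATTGACA, an octamer read from them after their scores were seen. Its 152 carriers had median log2 fold changes of -0.11 in U2OS and -0.13 in 143B, against 0.051 and 0.045 for 5958 genes with neither heptamer, and 44.1% of carriers were below 0 in both lines, against 22.9%. The 662 genes with either or both heptamers but not the octamer had medians of 0.047 and -0.060. In U2OS that was near the median of genes with neither. Unlike the scores, these medians were not corrected for the length and GC content of the 3' UTR. They therefore do not show whether the 662 genes were shifted in U2OS. Named genes with a single heptamer went both ways: MN1 and B2M were lower in both lines, SHQ1 was higher in both, and LMNB1 and PMAIP1 were higher in U2OS and lower in 143B. IGF2BP1 was higher in 143B, but at 0.23 and 0.29 FPKM in U2OS it was under the filter of 1 FPKM. YTHDC1 had log2 fold changes of 0.20 in U2OS and 0.21 in 143B, but 0.02 and -0.02 with length-weighted values. SLC7A11, which holds the octamer, had log2 fold changes of 0.11 and -1.52, and ZDHHC20, which also holds it, -1.27 and -1.41. METTL14's own transcript holds CATTGAC once in its coding part and once in its 3' UTR, and ATTGACA once in each UTR, but not the octamer, and 29.4% of the scanned heptamers occur in METTL14 transcripts.

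The octamer may mark off-target pairing of the shared hairpin, which acts through a short seed as microRNAs do. The heptamer with the lowest score in U2OS scored -5.74 in 143B, an independent pair of libraries, the second lowest of all. Of 30 searched genes lower in both lines, 5 hold either heptamer (percentile 84.2 of sets matched on 3' UTR length) and 4 hold the octamer (percentile 99.8). The octamer was read from these same fold changes, so its percentile is no independent support. Pairing at these heptamers in the searched 3' UTRs, as the source of all shared decreases, is argued against by the 25 genes with neither heptamer. Independent lists would share 6.96 of these, a low baseline, since 33 genes with neither heptamer went at least 2-fold in opposite ways. Coding parts, other transcripts and indirect effects of the hairpin were not searched, so off-target action on the 25 genes stays open. Variable genes with no common direction are argued against as the only source, since 74 shared 2-fold genes went the same way and 39 opposite ways. They can be part of it, because opposite genes also exceeded independent lists, at 20 and 19 against 8.60 and 7.48. The share going the same way was at least 60.6% in each setting that sums transcripts. These settings reuse the same 4 libraries, and some hold few shared genes. With the largest transcript alone that share was 51.4%, so the argument holds for gene sums only. Assignment of fragments between transcripts stays undecided. Of 53 shared genes with more than 1 listed transcript, 71.7% kept their call with length-weighted values, under the bound of 75%; the share was 79.7% with the 21 genes of 1 transcript, which cannot lose it. A response to lower METTL14 common to both lines stays open, untested, as does any other small RNA with that seed, since the hairpin's sequence is not given in the sources used here.

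The lower collagen and matrix list in U2OS did not follow GC content as far as this test shows, although the U2OS fold changes had a Spearman correlation of -0.16 with GC content across genes. Corrected for it, the list's median was -0.46, against -0.44. With length-weighted values the median was -0.31. Over the 19 members with more than 1 listed transcript it was -0.32, against -0.54, short of the bound of 3/4 that would have argued against the assignment of fragments between transcripts, so that source stays undecided. A replacement criterion was tried after that outcome was seen, the percentile among random lists, and at 0.01 it pointed the other way. It is not used for a verdict, because it was picked knowing the first result. Part of the size of the difference therefore depends on how gene values are formed. In 143B the list's median was -0.17 at percentile 3.03, inside the central 95%. A response of the cells and a difference between single cultures stay open.

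A further hypothesis was that transcripts lower in both lines carry more m6A consensus motifs (DRACH). Their median density of 19.3 motifs per kb of whole transcript was at percentile 73.3 of sets matched on 3' UTR length, whose median was 18.8. The sets were not matched on the length of the whole transcript. Genes higher in both lines had a median density of 18.9, at percentile 55.2 of their own sets. Across 10176 genes the density had Spearman correlations of 0.08 with the fold change in U2OS and -0.03 in 143B. A motif is not a methylated site, so this leaves the hypothesis undecided.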
